A study of Mus musculus with 35 samples.

How the data were processed

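Tracheal tissue RNA from mice was measured on 35 Affymetrix arrays in 7 groups of 5 arrays. The groups were untransplanted (native) trachea, and tracheas 4, 14 or 25 days after transplantation into MHC-compatible recipients (isografts) or MHC-incompatible recipients (allografts). Per the labels, RNA was isolated with TRIzol, cleaned on columns and labelled with biotin as cRNA. The deposited values are log2 intensities made by the authors with GCRMA 1.1.3, a method that subtracts a modelled background, normalizes the arrays and summarises the probes of a probe set. They ran from 0.317 to 15.53, and no further logarithm or pseudocount was applied. No detection calls were used, so values of about 2 to 4 were taken as near background. Folds against such values depend on the authors' background model.

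The table held 22690 probe sets. After 64 controls were set aside, 22626 remained, of which 20380 named 1 gene, 691 named several genes and 1555 had no gene in the annotation used and are unnamed here. Together they covered 12393 genes. A probe set was tested when its log2 value was at least 5 in at least 5 of the 35 arrays, which kept 13678 probe sets, 12521 of them with 1 gene and covering 8313 genes. Probe sets with several or no genes were counted but not named. A gene was represented by its probe set with the highest mean over all arrays.

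Group means were fitted to all 35 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 28 residual and 32 total degrees of freedom). Allografts were compared with isografts at each day, each graft group was compared with native trachea, and changes of the allograft-isograft difference between days were tested as interaction terms. In these comparisons "rose" and "fell" mean higher or lower in the first group named, or a change of the difference. They do not describe a course over time within a group. A probe set was called when its Benjamini-Hochberg adjusted p was under 0.05 within its comparison. Camera and hypergeometric p-values compare genes, and all others measure the spread between arrays, not known to be separate animals. The small number of arrays per group limits the precision. The 6 comparisons with native trachea share the same 5 native arrays, so they are not independent of each other. In simulated values for 35 arrays, with changes added to the day 4 allografts, limma recovered 59% of 100 probe sets changed by log2 1 and 95% of 100 changed by log2 2, with 6 false calls.

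Before the data were examined, 32 gene lists, the groups, the filter, the comparisons, the rule for naming genes and all alternatives except the removal of arrays that stood apart were fixed. The lists covered T cells, cytotoxic and NK cells, B and plasma cells, macrophages and monocytes, neutrophils, dendritic cells, mast cells, the interferon-gamma and type I interferon responses, MHC class I and class II, immune checkpoints and regulatory T cells, acute inflammation, alternative activation and type 2 cytokines, and complement. They also covered general, secretory, ciliated, and basal and squamous epithelium, extracellular matrix and fibrosis, smooth muscle and myofibroblasts, cartilage, endothelium, cell cycle, hypoxia and glycolysis, and xenobiotic and retinoid metabolism. Markers of neighbouring tissue (skeletal muscle, thyroid, adipocytes and skin), sex-linked genes and scaling reference genes completed them. The 31 lists with at least 4 measured members were tested against the other genes with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and limma's rotation test fry were run beside it. The thyroid list had 2 measured members and was not tested as a list. List levels were also compared per array with an exact two-sided permutation test over 252 assignments.

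Named genes followed a fixed rule. For each allograft-isograft comparison they were the 2 members of every called list with the largest difference in its direction, and the 6 largest rises and 6 largest falls among called genes whose arrays did not overlap. For each comparison with native trachea they were 1 member per called list and the 4 largest rises and falls, and for each interaction the 5 largest changes either way. Cd3e, Cd8a, Gzmb, Ifng, Cxcl9, Ighm, Scgb1a1, Foxj1, Krt5, Acta2, Col1a1 and Col2a1 belonged to every comparison. Ifng lay below the filter, so its values carry no adjusted p unless the unfiltered fit is named.

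Alternatives were no filter, a stricter filter (log2 7), array weights, an intensity trend with robust variance, repeated quantile normalization, centring on the median of the probe sets kept or on the scaling reference genes, and a replicate-number block. Further ones were fits on the compared arrays alone, an adjusted p under 0.01, a 2-fold minimum, the mean of a gene's probe sets, and leaving out each array in turn.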

Results

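The data describe gene expression in native mouse trachea and heterotopic isografts and allografts at days 4, 14 and 25 (7 groups of 5 arrays). Array medians lay between 5.07 and 5.30 on the log2 scale, and 51.0% to 54.3% of the values per array were at least 5. The correlation between arrays of the same group had a median of 0.935, against 0.852 between groups. Native replicate 5 and day 25 isograft replicate 5 stood apart, with median correlations of 0.894 and 0.854 with their own groups. Both arrays also held the highest skin marker levels of their groups, with 9.21 in the native array against 3.75 to 4.06 in its group.

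The comparison of allografts with isografts at day 4 asked how MHC mismatch between donor and recipient showed in the first days of a graft. Interferon-gamma response genes rose in allografts. Cxcl9, a chemokine that attracts activated T cells, rose by 5.10 on the log2 scale (34.3-fold, SE 0.41, n = 5 per group), from 3.83 (SD 0.70) to 8.93 (SD 0.92). Iigp1, an interferon-inducible GTPase that acts against intracellular pathogens, rose by 2.81 (SE 0.34). The guanylate-binding proteins Gbp2 and Gbp6 rose by 2.75 (SE 0.31) and 2.58 (SE 0.37). In total 82 of 13678 probe sets differed, 67 higher and 15 lower in allografts, and 75 of them by at least 2-fold.

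At day 4, 13 of 24 interferon-gamma response genes were called higher and 11 were not called, with 19 higher when adjusted over the list alone. Their mean difference was 1.497 (adjusted p = 2.2e-51, and adjusted p = 6.86e-05 with an estimated correlation). This was the 1 list of the 8 called at day 4 that held with an estimated correlation. Cytotoxic and NK cell genes had a mean difference of 0.43 (adjusted p = 0.00262), with 1 of 11 called higher and 3 when adjusted over the list alone, but adjusted p = 0.459 with an estimated correlation. Another 12 genes of this list lay below the filter, and without a filter its mean was 0.177 (adjusted p = 0.0359, range over its alternatives 6.34e-05 to 0.459). Its called member was Klrd1, an NK cell receptor chain, which rose by 2.01 (SE 0.27). Type I interferon response genes had a mean of 0.61 (adjusted p = 2.07e-06), with 1 of 21 called and 7 when adjusted over the list alone, but adjusted p = 0.459 with an estimated correlation. Oasl2, an antiviral 2'-5' oligoadenylate synthetase-like protein, rose by 1.46 (SE 0.33, adjusted p = 0.0187). Its call was lost without any 1 of allograft replicates 1, 2, 3 or 5 or isograft replicates 2 or 4 (1.31 to 1.42, adjusted p 0.0567 to 0.107).

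Macrophage and monocyte genes had a mean difference of 0.34 at day 4 (adjusted p = 0.00385, but adjusted p = 0.94 with an estimated correlation). Of their 23 genes 1 was called higher, and 4 when adjusted over the list alone. C1qb, a chain of complement C1q, rose by 1.17 (SE 0.25, adjusted p = 0.0111), but not without allograft replicate 3 (1.01, adjusted p = 0.0733) or isograft replicate 1 (1.04, adjusted p = 0.0612). MHC class I genes had a mean of 0.41 (adjusted p = 0.00718), with 1 of 9 called, and adjusted p = 0.377 with an estimated correlation. That list's call was lost without allograft replicate 1 (0.36, adjusted p = 0.0516) or isograft replicate 4 (0.355, adjusted p = 0.0659). Tap1, which carries peptides to MHC class I, rose by 1.88 (SE 0.28). For dendritic cell genes the mean was 0.37 (adjusted p = 0.0187), no member of 12 was called and 1 was higher when adjusted over the list alone, with adjusted p = 0.459 with an estimated correlation. The dendritic call was lost without allograft replicates 1 or 2 or isograft replicate 4 (0.33 to 0.36, adjusted p 0.0547 to 0.0998).

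Lists lower in day 4 allografts were hypoxia and glycolysis (mean -0.41, adjusted p = 1.11e-09, 1 of 23 called lower) and general epithelium (mean -0.18, adjusted p = 0.0187, none of 27 called). With an estimated correlation these gave adjusted p = 0.0767 and adjusted p = 0.94. The epithelial call was lost without allograft replicates 1 or 4 or isograft replicates 1 or 4 (-0.16 to -0.05, adjusted p 0.0547 to 0.466). Ndrg1, a hypoxia-responsive gene, fell by 1.22 (SE 0.29, adjusted p = 0.04), and lost its call without any 1 of allograft replicates 1, 2, 3 or 5 or isograft replicates 2, 3 or 5 (-1.27 to -1.08, adjusted p 0.0679 to 0.195). T cell genes had a mean of 0.01 (adjusted p = 0.819), neutrophil genes 0.03 (adjusted p = 0.891), and secretory epithelium -0.11 (adjusted p = 0.476), the last called lower without isograft replicate 2 (-0.31, adjusted p = 0.0197). Skin markers, sex-linked genes and scaling reference genes had means of 0.31, 0.115 and -0.05 (adjusted p = 0.891, 0.956 and 0.306), with no member called by limma in any of the 3 lists. The skin mean came from 5 of 16 markers and was -0.033 without a filter.

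Among the largest day 4 differences, Rpgrip1, a ciliary protein of photoreceptors, rose by 5.77 (SE 0.43), from 4.42 (SD 0.93) to 10.19 (SD 0.48). Its other probe sets lay between 2.44 and 4.3 in all arrays of the series. Trim34a, an interferon-inducible tripartite motif protein, rose by 2.78 (SE 0.29). Its other probe set ran from 4.24 to 5.5 in the allografts of all days and from 3.7 to 5.63 in the other arrays. Hal, which breaks down histidine, fell by 4.28 (SE 0.46), to 2.89 (SD 0.14). H2-Ea, an alpha chain of MHC class II, fell by 2.03 (SE 0.21) and Ifi44l, an interferon-induced gene, by 2.03 (SE 0.34). Eno2, a glycolytic enolase, fell by 1.44 (SE 0.31), but not without isograft replicate 5 (-1.18, adjusted p = 0.0764). The actin regulator Cap1 fell by 1.27 (SE 0.28), but not without isograft replicate 1 (-1.11, adjusted p = 0.0789). Ctse, the protease cathepsin E, fell by 0.86 (SE 0.20, adjusted p = 0.0319), with its call lost in 8 of the 10 omissions of an array, all but those of allograft replicate 5 and isograft replicate 1 (-0.90 to -0.77, adjusted p 0.053 to 0.146).

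Gzmb, the cytotoxic protease granzyme B, differed by 0.92 (SE 0.28, adjusted p = 0.246) at day 4, and was called higher without isograft replicate 3 (1.17, adjusted p = 0.0279). Ighm, the immunoglobulin M heavy chain, differed by 2.21 (SE 0.76, adjusted p = 0.446). The T cell genes Cd3e and Cd8a differed by -0.06 (SE 0.28) and 0.01 (SE 0.31), and Ifng by 0.10 (SE 0.22). Scgb1a1 (club cell secretoglobin) differed by 0.18 (SE 0.53), Foxj1 (a regulator of ciliated cells) by -0.07 (SE 0.45), and Krt5 (basal cell keratin) by -0.04 (SE 0.59). Acta2 (smooth muscle actin), Col1a1 (fibrillar collagen) and Col2a1 (cartilage collagen) differed by 0.14 (SE 0.23), 0.01 (SE 0.31) and -0.07 (SE 0.56). The count of called probe sets was 51 when the 10 arrays of these groups were fitted alone.

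At day 14 the same comparison asked how the grafts differed midway through the series. Cytotoxic, interferon-gamma and checkpoint genes rose in allografts, and genes of secretory and ciliated epithelium fell. Gzmb rose by 4.51 (SE 0.28, n = 5 per group), Cxcl9 by 5.15 (SE 0.41), and Ido1, a tryptophan-degrading enzyme that restrains T cells, by 5.33 (SE 0.33). The airway secretoglobin Scgb3a2 fell by 8.44 (SE 0.56), from 13.67 (SD 0.09) to 5.23 (SD 0.99). Foxa1, a transcription factor of endodermal epithelium, fell by 4.85 (SE 0.38). In all, 2514 probe sets differed, 1371 higher and 1143 lower, and 1496 of them by at least 2-fold. With arrays centred on the scaling reference genes the split was 935 higher and 1326 lower, with the median of all probe sets shifted by -0.11.

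Of the cytotoxic and NK cell genes, 9 of 11 rose at day 14 (mean 2.22, or 1.558 without a filter, adjusted p = 2.98e-12, and adjusted p = 0.00794 with an estimated correlation). Nkg7, a granule protein of killer cells, rose by 3.64 (SE 0.30). Interferon-gamma response genes rose in 22 of 24 cases, 23 when adjusted over the list alone (mean 2.36, adjusted p = 4.58e-25, and adjusted p = 0.00339 with an estimated correlation). All 9 MHC class I genes rose (mean 1.16, adjusted p = 1.22e-06, and adjusted p = 0.0101 with an estimated correlation), among them the peptide transporters Tap1 by 2.65 (SE 0.28) and Tap2 by 1.34 (SE 0.28). Of 16 checkpoint and regulatory T cell genes on the array 4 passed the filter, and these 4 rose (mean 2.76, adjusted p = 2.73e-06, and adjusted p = 0.00339 with an estimated correlation). Without a filter the mean of this list was 0.956 (adjusted p = 2.76e-07, range over its alternatives 4.88e-13 to 0.00339). Cd274, the inhibitory ligand PD-L1, rose by 3.46 (SE 0.43). Ifng itself differed by 2.07 (SE 0.22) below the filter, with adjusted p = 2.78e-08 in the unfiltered fit.

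Cell cycle genes rose in 29 of 36 cases at day 14, 32 when adjusted over the list alone (mean 1.37, adjusted p = 8.3e-17, and adjusted p = 0.0422 with an estimated correlation). Top2a, which untangles DNA, rose by 2.99 (SE 0.43), and Birc5, a mitotic survival protein, by 2.64 (SE 0.44).

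Secretory epithelium fell in 17 of 19 genes at day 14, with 2 not called (mean -4.81, adjusted p = 2.57e-27, and adjusted p = 0.00339 with an estimated correlation). Dmbt1, a mucosal defence protein, fell by 8.20 (SE 0.50), Scgb3a1 by 7.92 (SE 0.51), Bpifa1, a secreted antimicrobial protein of the airway, by 7.70 (SE 0.43), and Scgb1a1 by 6.85 (SE 0.53). All 9 ciliated epithelium genes fell (mean -2.65, adjusted p = 1.09e-11, and adjusted p = 0.016 with an estimated correlation). The level of this list at days 4 and 14 was 5.01 and 4.8 in allografts, and 5.02 and 7.45 in isografts. Rsph1, a radial spoke protein, fell by 3.58 (SE 0.41), Tppp3, a microtubule protein, by 3.54 (SE 0.45), and Foxj1 by 2.76 (SE 0.45). General epithelium fell in 21 of 27 genes (mean -1.81, adjusted p = 5.11e-16, and adjusted p = 0.0166 with an estimated correlation), with the adhesion molecule Epcam lower by -3.65 (SE 0.47). Xenobiotic and retinoid metabolism fell in 13 of 28 genes, 18 when adjusted over the list alone, while 1 rose (mean -1.52, adjusted p = 8.35e-09, and adjusted p = 0.0227 with an estimated correlation). Aldh1a1, a retinal dehydrogenase, fell by 5.42 (SE 0.51) and the club cell cytochrome Cyp2f2 by 5.31 (SE 0.71).

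Several immune lists passed camera at day 14 but not with an estimated correlation. T cell genes rose in 6 of 13 cases (mean 0.99, adjusted p = 0.000275, but adjusted p = 0.172 with an estimated correlation), with the T cell receptor chains Cd3d up by 3.15 (SE 0.48), Cd3g by 2.33 (SE 0.40) and Cd3e by 1.39 (SE 0.28). Macrophage and monocyte genes were higher in 12 and lower in 1 of 23 (mean 0.91, adjusted p = 1.98e-05, but adjusted p = 0.217 with an estimated correlation). The Fc receptor Fcgr1 rose by 2.76 (SE 0.45) and the scavenger receptor Msr1 by 1.93 (SE 0.44). Neutrophil genes were higher in 4 and lower in 1 of 10 (mean 0.98, adjusted p = 0.023, but adjusted p = 0.273 with an estimated correlation). That call was lost without allograft replicate 2 or isograft replicates 1 or 4 (0.82 to 0.92, adjusted p 0.0504 to 0.0691). Mmp9, a gelatinase, rose by 3.23 (SE 0.61), and Fpr2, a formyl peptide receptor, by 2.59 (SE 0.60).

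Dendritic cell genes rose in 4 of 12 cases at day 14, 5 when adjusted over the list alone (mean 0.52, adjusted p = 0.0146, but adjusted p = 0.217 with an estimated correlation). The costimulator Cd86 rose by 1.38 (SE 0.27). The homing receptor Ccr7 rose by 1.06 (SE 0.36, adjusted p = 0.0351), a call lost without any 1 of allograft replicates 3, 4 or 5 or isograft replicates 1, 2, 4 or 5 (0.76 to 1.08, adjusted p 0.0522 to 0.152). MHC class II genes were higher in 5 and lower in 1 of 8 (mean 0.69, adjusted p = 0.00931, but adjusted p = 0.217 with an estimated correlation), with H2-DMa, which loads peptides, up by 2.32 (SE 0.42) and H2-Ab1 by 1.20 (SE 0.23). Type I interferon response genes rose in 6 of 21 cases, 10 when adjusted over the list alone (mean 0.77, adjusted p = 0.000475, but adjusted p = 0.273 with an estimated correlation). Trim30a rose by 1.83 (SE 0.34) and Oasl2 by 1.70 (SE 0.33).

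Acute inflammation genes rose in 12 of 20 cases at day 14 (mean 1.36, adjusted p = 5e-06, but adjusted p = 0.158 with an estimated correlation), with the acute phase protein Saa3 up by 3.36 (SE 0.77) and the monocyte chemokine Ccl7 by 3.11 (SE 0.46). Complement genes were higher in 9 and lower in 1 of 13 (mean 1.10, adjusted p = 2.1e-05, but adjusted p = 0.113 with an estimated correlation), among them properdin, Cfp, by 2.32 (SE 0.42) and C1qc by 1.78 (SE 0.30). Matrix and fibrosis genes were higher in 10 and lower in 1 of 31, 18 higher when adjusted over the list alone (mean 0.76, adjusted p = 1.47e-05, but adjusted p = 0.247 with an estimated correlation). The metalloproteinase inhibitor Timp1 rose by 2.49 (SE 0.50) and the matrix protein Tgfbi by 2.35 (SE 0.28). Col1a1 rose by 0.93 (SE 0.31, adjusted p = 0.0352), but lost its call in 7 omissions of an array, those of allograft replicates 1, 2, 4 and 5 and isograft replicates 2, 3 and 4 (0.73 to 0.94, adjusted p 0.0552 to 0.127). Its mean over all probe sets differed by 0.12 (adjusted p = 0.806).

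Cartilage genes fell in 14 of 21 cases at day 14, 19 when adjusted over the list alone (mean -2.06, adjusted p = 5.41e-11, but adjusted p = 0.122 with an estimated correlation). Chad, a cartilage matrix protein, fell by 3.83 (SE 0.48), Mia, secreted by chondrocytes, by 3.73 (SE 0.62), and Col2a1 by 2.17 (SE 0.56). Skeletal muscle markers, a sign of neighbouring tissue, fell in 12 of 23 cases (mean -3.28, adjusted p = 6.15e-07, but adjusted p = 0.274 with an estimated correlation), with the myosin Myh1 lower by -6.48 (SE 1.39) and the troponin Tnnc2 by -6.12 (SE 1.73). Basal and squamous epithelium was lower in 7 and higher in 1 of 21 (mean -0.65, adjusted p = 0.023, but adjusted p = 0.54 with an estimated correlation), a call lost without allograft replicate 5 or isograft replicates 2, 3 or 4 (-0.47 to -0.30, adjusted p 0.0527 to 0.129). The basal keratin Krt15 fell by 3.93 (SE 0.62) and the basal cell regulator Trp63 by 2.32 (SE 0.33), while Krt5 differed by -0.54 (SE 0.59, adjusted p = 0.611). Hypoxia and glycolysis genes rose in 9 of 23 cases (mean 0.55, adjusted p = 0.00086, but adjusted p = 0.217 with an estimated correlation). Pdk1, which diverts pyruvate from mitochondria, rose by 1.91 (SE 0.25), and the carbonic anhydrase Car9 by 1.44 (SE 0.42, adjusted p = 0.0137), but not without allograft replicate 3 (1.23, adjusted p = 0.0546) or isograft replicate 1 (1.16, adjusted p = 0.0583).

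The largest day 14 rises also included Rpgrip1 by 6.69 (SE 0.43, not on its other probe sets), Ubd, a cytokine-induced ubiquitin-like protein, by 4.80 (SE 0.21), and Gbp8 by 4.63 (SE 0.40). The largest falls included Pth, parathyroid hormone, by 8.95 (SE 0.86) and Tg, thyroglobulin, by 8.36 (SE 0.55), both products of neck glands beside the trachea. Both measured thyroid genes fell, and 15 adipocyte markers had a mean difference of -0.06 (adjusted p = 0.722). Ighm rose by 3.43 (SE 0.76), while the B and plasma cell list had 2 of 8 genes higher (mean 0.90, adjusted p = 0.112 by camera). Per array the exact permutation test separated the levels of this list (exact p = 0.0159, adjusted p = 0.0347). Cd8a differed by 0.63 (SE 0.31, adjusted p = 0.171) and Acta2 by 0.31 (SE 0.23, adjusted p = 0.41). Of the genes represented by several probe sets, 8 were called in opposite directions by different probe sets, among them Itgb1 and H2-D1.

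At day 25 the comparison asked how late allografts differed from late isografts. Genes of secretory, ciliated and general epithelium fell, and genes of cytotoxic cells, B and plasma cells and antigen presentation rose. Bpifa1 fell by 11.62 (SE 0.43, n = 5 per group), from 14.70 (SD 0.30) to 3.09 (SD 0.20), and Scgb1a1 by 9.76 (SE 0.53). The immunoglobulin genes Iglv1 and Ighm rose by 5.16 (SE 0.60) and 4.21 (SE 0.76), and Cxcl9 by 6.21 (SE 0.41). Altogether 2039 probe sets differed, 872 higher and 1167 lower, and 1251 of them by at least 2-fold. The split was 631 higher and 1254 lower with arrays centred on the scaling reference genes.

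Secretory epithelium was lower in 17 of 19 genes at day 25, 18 when adjusted over the list alone (mean -5.88, adjusted p = 6.96e-33, and adjusted p = 0.00116 with an estimated correlation), with Scgb3a1 lower by -10.21 (SE 0.51). Ltf, the iron-binding lactoferrin, fell by 9.96 (SE 0.53). General epithelium was lower in 24 of 27 genes, 25 when adjusted over the list alone (mean -3.62, adjusted p = 3.88e-34, and adjusted p = 0.00116 with an estimated correlation). Foxa1 fell by 6.85 (SE 0.38) and the desmosomal protein Dsp by 6.74 (SE 0.58). All 9 ciliated genes fell (mean -2.40, adjusted p = 9.56e-10, and adjusted p = 0.0323 with an estimated correlation), among them Foxj1 by 3.40 (SE 0.45) and Rsph1 by 3.18 (SE 0.41). Basal and squamous epithelium was lower in 9 of 21 genes, 11 when adjusted over the list alone (mean -2.15, adjusted p = 3.37e-07, but adjusted p = 0.184 with an estimated correlation), with Krt15 lower by -5.69 (SE 0.62) and Krt5 by -4.98 (SE 0.59). Isograft replicate 5, with the highest skin markers of its group, had a basal level of 8.95 against 4.82 to 5.55 and a secretory level of 9.42 against 10.93 to 11.28 in the other isografts. Xenobiotic and retinoid metabolism was lower in 12 and higher in 1 of 28 genes (mean -1.36, adjusted p = 1.8e-06, but adjusted p = 0.0526 with an estimated correlation). The glutathione transferase Gsta4 fell by 5.60 (SE 0.65) and Cyp2f2 by 5.31 (SE 0.71).

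Cytotoxic and NK cell genes rose in 9 of 11 cases at day 25, 10 when adjusted over the list alone (mean 2.15, or 1.421 without a filter, adjusted p = 6.11e-14, and adjusted p = 0.00512 with an estimated correlation), with Klrd1 up by 3.49 (SE 0.27) and Gzmb by 3.32 (SE 0.28). B and plasma cell genes rose in 7 of 8 cases (mean 2.39, adjusted p = 6e-07, and adjusted p = 0.0323 with an estimated correlation). Interferon-gamma response genes rose in 18 of 24 cases (mean 1.65, adjusted p = 8.64e-17, and adjusted p = 0.0158 with an estimated correlation), Gbp2 among them by 2.98 (SE 0.31). MHC class II genes rose in 7 of 8 cases, with H2-Ea lower (mean 1.25, adjusted p = 3.05e-06, and adjusted p = 0.0323 with an estimated correlation). H2-DMa rose by 3.11 (SE 0.42) and H2-Aa by 2.08 (SE 0.24). MHC class I genes rose in 7 of 9 cases (mean 0.99, adjusted p = 3.5e-06, and adjusted p = 0.0158 with an estimated correlation), with Tap1 up by 2.17 (SE 0.28) and H2-Q10 by 1.73 (SE 0.43). Dendritic cell genes rose in 6 of 12 cases (mean 0.82, adjusted p = 2.07e-05, and adjusted p = 0.0346 with an estimated correlation), Cd86 by 1.47 (SE 0.27) and the lectin Clec10a by 1.37 (SE 0.36). Checkpoint genes rose in 2 of the 4 measured of 16 (mean 1.00, or 0.532 without a filter, adjusted p = 0.00775, and adjusted p = 0.0458 with an estimated correlation), Cd274 by 1.89 (SE 0.43) and the regulatory T cell receptor Tnfrsf18 by 1.25 (SE 0.20).

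T cell genes rose in 7 of 13 cases at day 25 (mean 0.99, adjusted p = 3.5e-06, but adjusted p = 0.0647 with an estimated correlation). Cd3d rose by 1.86 (SE 0.48), Cd3g by 1.85 (SE 0.40), and Cd3e by 0.96 (SE 0.28, adjusted p = 0.0148), the last not without allograft replicate 4 (0.82, adjusted p = 0.0559). Macrophage and monocyte genes were higher in 12 and lower in 2 of 23 (mean 0.92, adjusted p = 1.8e-06, but adjusted p = 0.152 with an estimated correlation), with the macrophage marker Adgre1 up by 2.40 (SE 0.23) and Ly86, a partner of a Toll-like receptor homologue, by 2.38 (SE 0.39). Complement genes were higher in 7 and lower in 1 of 13 (mean 0.93, adjusted p = 5.52e-05, but adjusted p = 0.103 with an estimated correlation), C1qb by 2.25 (SE 0.25) and C1qc by 1.72 (SE 0.30). Cd8a differed by 0.40 (SE 0.31, adjusted p = 0.478). Ifng differed by 0.85 (SE 0.22), with adjusted p = 0.00778 in the unfiltered fit.

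Matrix and fibrosis genes rose in 15 of 31 cases at day 25, 19 when adjusted over the list alone (mean 0.79, adjusted p = 3.38e-08, but adjusted p = 0.131 with an estimated correlation). Postn, a matrix protein of remodelling tissue, rose by 1.83 (SE 0.30). Thbs1, thrombospondin, rose by 1.84 (SE 0.60, adjusted p = 0.0317), but lost its call without any 1 of allograft replicates 1, 3 or 5 or isograft replicates 1, 2 or 4 (1.59 to 1.84, adjusted p 0.0517 to 0.104). Col1a1 differed by 0.81 (SE 0.31, adjusted p = 0.0841), and was called higher without isograft replicate 5 (1.08, adjusted p = 0.0117). Smooth muscle and myofibroblast genes were lower in 8 and higher in 1 of 15, 12 lower when adjusted over the list alone (mean -1.28, adjusted p = 1.7e-05, but adjusted p = 0.0959 with an estimated correlation). The contractile genes Cnn1, Myh11 and Acta2 fell by 3.25 (SE 0.52), 2.53 (SE 0.56) and 1.29 (SE 0.23). Cartilage genes had a mean of 0.77 (adjusted p = 0.00684, but adjusted p = 0.579 with an estimated correlation), with 1 higher and 1 lower of 21. This call was lost without isograft replicate 1 (0.505, adjusted p = 0.0942). Col11a1, a cartilage collagen, rose by 1.46 (SE 0.51, adjusted p = 0.0483), but kept its call in only 1 of the 10 omissions of an array, that of isograft replicate 5 (1.17 to 1.56, adjusted p 0.0518 to 0.145 in the others), and Col2a1 differed by 0.99 (SE 0.56, adjusted p = 0.28).

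The largest day 25 rises also held Rpgrip1 by 6.98 (SE 0.43), Trim34a by 4.09 (SE 0.29) and Gbp8 by 4.07 (SE 0.40). The other probe sets of Rpgrip1 and Trim34a did not separate allografts from the other arrays. Tg fell by 9.86 (SE 0.55) and Pth fell by 9.24 (SE 0.86). Neutrophil genes had a mean of -1.31 (adjusted p = 0.157 by camera), with 3 of 10 lower. Per array the exact permutation test separated the neutrophil levels (exact p = 0.0159, adjusted p = 0.0347). The neutrophil list includes Ltf, whose large fall is given above, so its level does not by itself show fewer neutrophils. Type I interferon response genes had a mean of 0.34 (adjusted p = 0.0599), but were called without isograft replicate 1 (0.605, adjusted p = 0.00137). They were also called without a filter, with the stricter filter, with array weights, with centring on the scaling reference genes, with the replicate block and with the mean of a gene's probe sets (0.277 to 0.51, adjusted p 0.00959 to 0.0458, range over all alternatives 0.00137 to 0.655, the highest with an estimated correlation). Cell cycle genes had a mean of 0.11 (adjusted p = 0.24), and were called without isograft replicate 5 (0.30, adjusted p = 0.0108) and with array weights (0.405, adjusted p = 0.00206). Acute inflammation genes had a mean of 0.06 (adjusted p = 0.435), and were called with array weights (0.495, adjusted p = 0.0399, the lowest of their alternatives).

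**Figure D1:**
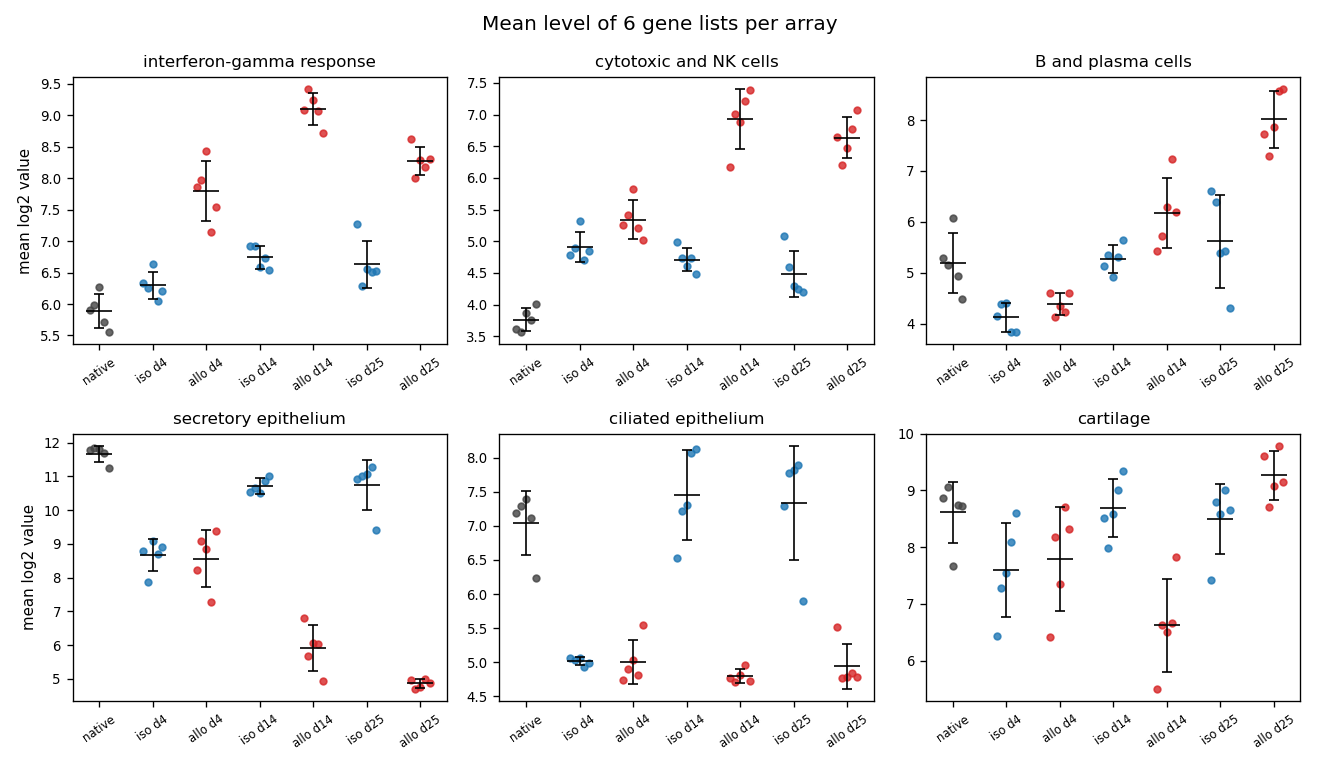
Mean log2 value of 6 gene lists (vertical axis) in each of the 35 arrays, by group (horizontal axis; native, isograft and allograft at days 4, 14 and 25). Points are arrays, bars are group means with SD, and secretory epithelium lies at 4.87 in day 25 allografts against 10.74 in day 25 isografts.

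Genes were shared between days. Of 39 genes higher at day 4, 36 were also higher at day 14 (4.2 by independent lists) and 35 at day 25 (2.7). Of the 7 genes lower at day 4, 5 were lower at day 14 and 5 at day 25 (0.7 by independent lists for each). Per array, an exact permutation test separated the list levels of allografts and isografts for 3 lists at day 4, 23 at day 14 and 18 at day 25 (adjusted over the lists and days), among them secretory epithelium at days 14 and 25 (exact p = 0.00794, the smallest possible with 252 assignments). Days 14 and 25 shared 395 of 568 higher genes (61.4 by independent lists) and 554 of 858 lower genes (89.7), and 2 genes went in opposite directions.

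The change of the allograft-isograft difference from day 4 to day 14 was tested as an interaction. The difference of Gzmb grew by 3.59 (SE 0.40), of Ido1 by 5.53 (SE 0.47) and of Ubd by 3.78 (SE 0.29). Those of the secretory genes Scgb3a2, Dmbt1, Scgb3a1 and Scgb1a1 dropped by 8.37 (SE 0.79), 7.92 (SE 0.70), 7.60 (SE 0.71) and 7.03 (SE 0.75), while that of Pth dropped by 12.29 (SE 1.21) and that of Tg dropped by 9.04 (SE 0.78). Ccl7 rose by 3.62 (SE 0.65) and the proprotein convertase Pcsk5 by 3.62 (SE 0.54). Foxj1 fell by 2.69 (SE 0.64), and Cd3e rose by 1.45 (SE 0.39), a call lost without allograft replicate 4 of day 14 (1.20, adjusted p = 0.0504). Cxcl9, high in allografts at both days, changed its difference by 0.05 (SE 0.58, adjusted p = 0.983). In total 873 probe sets passed, 349 upward and 524 downward, against 182 and 604 with centring on the scaling reference genes (median shift -0.16).

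Of the 18 lists called for that change, 9 held with an estimated correlation. These were cytotoxic cells (1.79, adjusted p = 0.0198 with an estimated correlation, 8 of 11 genes upward, and 1.382 without a filter), MHC class I (0.75, 0.0489, none of 9 but 5 when adjusted over the list alone), checkpoints (2.52, 0.00175, 3 of the 4 measured of 16, and 0.966 without a filter), and cell cycle (1.38, 0.0397, 15 of 36). Hypoxia and glycolysis (0.95, 0.0397, 12 of 23 upward), general epithelium (-1.63, 0.0397, 12 of 27 downward), secretory epithelium (-4.70, 0.00175, 15 of 19), ciliated epithelium (-2.64, 0.0222, 9 of 9) and xenobiotic metabolism (-1.41, 0.0489, 9 of 28) completed them. Cartilage (-2.27, 10 of 21 downward) gave adjusted p = 0.119 with an estimated correlation, and the interferon-gamma response (0.87, 3 of 24 upward) gave adjusted p = 0.186 with an estimated correlation. The levels at days 4 and 14 show which group moved. Ciliated epithelium was at 5.01 and 4.8 in allografts against 5.02 and 7.45 in isografts. Xenobiotic metabolism was at 6.62 and 6.6 against 6.74 and 8.13, and cell cycle at 7.31 and 6.36 against 7.31 and 4.98. Secretory epithelium moved in both (8.56 and 5.91 against 8.67 and 10.72), and cytotoxic cells mainly in allografts (5.34 and 6.93 against 4.91 and 4.71).

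From day 14 to day 25 the difference of cartilage genes rose. Penk, a neuropeptide precursor, rose by 5.12 (SE 0.63), Otor by 4.88 (SE 0.77), Mia by 4.55 (SE 0.88), the collagen Col9a1 by 4.42 (SE 0.94) and the matrilin Matn4 by 4.23 (SE 0.69). Lactoferrin, Ltf, fell by 5.86 (SE 0.75), the epithelial keratins Krt19, Krt7 and Krt5 by 5.38 (SE 0.86), 4.95 (SE 0.75) and 4.44 (SE 0.83), and the secreted epithelial protein Wfdc2 by 4.80 (SE 0.75). Ido1 fell by 5.18 (SE 0.47), to 2.46 in day 25 allografts, and Acta2 by 1.60 (SE 0.32). Col2a1 rose by 3.17 (SE 0.79, adjusted p = 0.0421) and Scgb1a1 fell by 2.91 (SE 0.75, adjusted p = 0.0483). Of 20 omissions of an array, 13 ended the Col2a1 call (2.82 to 3.21, adjusted p 0.0537 to 0.0919), those of allograft replicates 1, 3 and 4 of either day, isograft replicates 1, 3, 4 and 5 of day 14 and isograft replicates 1, 2 and 3 of day 25. The Scgb1a1 call ended in 18 (-3.035 to -2.31, adjusted p 0.0557 to 0.0981), all but those of allograft replicate 2 of day 14 and isograft replicate 5 of day 25. In all, 146 probe sets passed, 60 upward and 86 downward, and 96 without allograft replicate 3 of day 14.

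Of the 18 lists called for the change from day 14 to day 25, 6 held with an estimated correlation. They were cartilage (2.84, adjusted p = 0.0155 with an estimated correlation, 12 of 21 genes upward), B and plasma cells (1.49, 0.0433, none of 8 but 4 when adjusted over the list alone), neutrophils (-2.30, 0.0155, 2 of 10 downward), checkpoints (-1.76, 0.0194, 1 of 4), general epithelium (-1.82, 0.0155, 10 of 27) and cell cycle (-1.27, 0.0229, 9 of 36). The checkpoint call, from 4 of 16 genes on the array, was lost without a filter (-0.424, adjusted p = 0.157, range over its alternatives 4.46e-05 to 0.157). Acute inflammation (-1.30, 3 of 20 downward) gave adjusted p = 0.194 with an estimated correlation.

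Between days 4 and 25 the differences of 3 immunoglobulin genes rose, Iglv1 by 5.31 (SE 0.84), the kappa variable gene Igkv9-120 by 3.59 (SE 0.87) and the heavy chain Ighg3 by 3.54 (SE 0.66). That of Ighm changed by 2.00 (SE 1.08, adjusted p = 0.405), and by 5.377 with the mean of its probe sets (adjusted p = 3.44e-08, the lowest of its alternatives). Egfl6, a secreted growth factor-like protein, rose by 3.41 (SE 0.53), the pattern recognition protein Ptx3 by 3.36 (SE 0.78), and Gzmb by 2.40 (SE 0.40). The differences of Pth (-12.59, SE 1.21), Bpifa1 (-11.26, SE 0.60), Tg (-10.54, SE 0.78), Scgb1a1 (-9.94, SE 0.75) and Scgb3a1 (-9.89, SE 0.71) fell. Krt5, Foxj1 and Acta2 fell by 4.94 (SE 0.83), 3.33 (SE 0.64) and 1.44 (SE 0.32). Here 708 probe sets passed, 169 upward and 539 downward, against 108 and 612 with centring on the scaling reference genes (median shift -0.115) and 244 and 485 with centring on array medians (0.121). Of the 19 lists called, 6 held with an estimated correlation: cytotoxic cells (1.72, adjusted p = 0.00789, and 1.245 without a filter), B and plasma cells (2.13, adjusted p = 0.0465), MHC class II (1.03, adjusted p = 0.0465), general epithelium (-3.45, adjusted p = 0.000601), secretory epithelium (-5.77, adjusted p = 0.000601) and ciliated epithelium (-2.39, adjusted p = 0.0451). Their called members numbered 7 of 11, 3 of 8, 5 of 8, 20 of 27, 15 of 19 and 7 of 9.

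**Figure D2:**
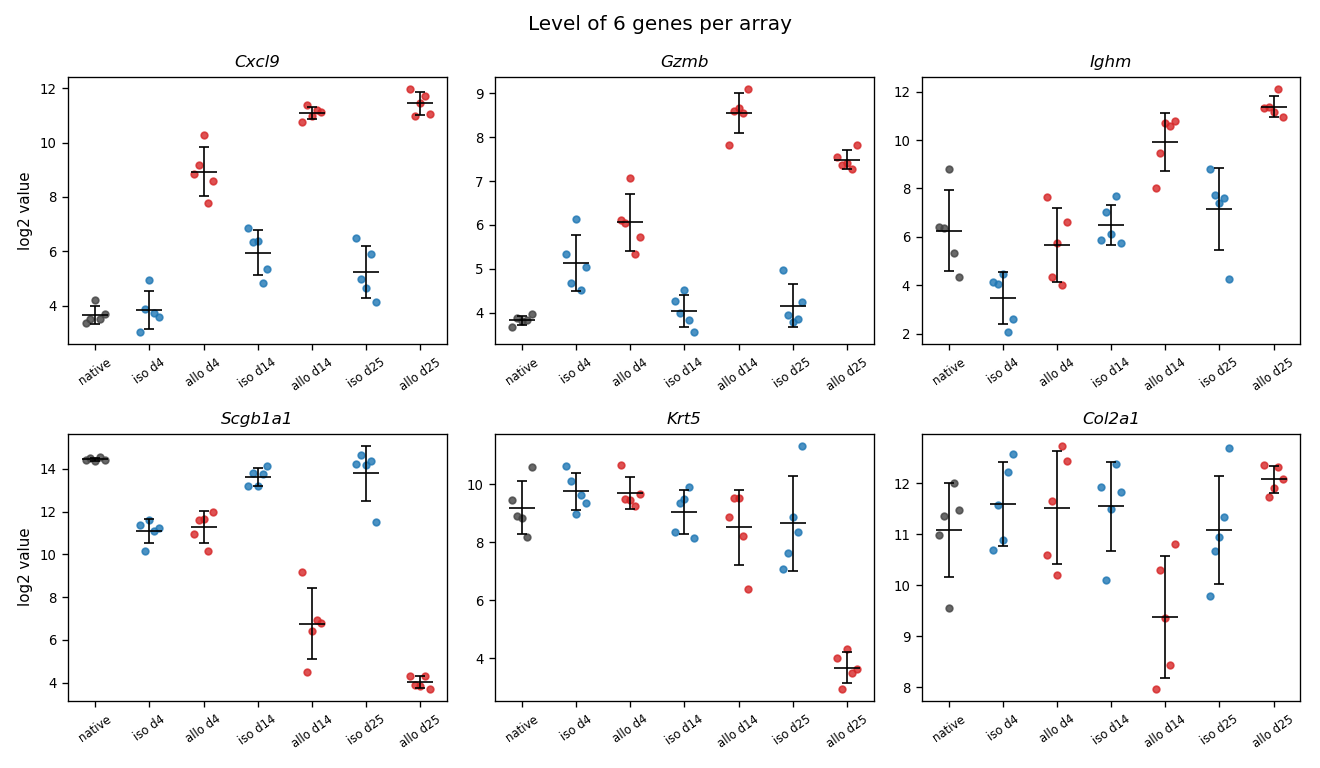
Log2 value of 6 genes (vertical axis) in each of the 35 arrays, by group (horizontal axis). Points are arrays, bars are group means with SD, and Krt5 lies at 3.68 in day 25 allografts against 8.52 in day 14 allografts.

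Isografts at day 4 were compared with native trachea to describe a graft without MHC mismatch. Cell cycle genes rose. Camera also called macrophage and acute inflammation genes higher and secretory and ciliated genes lower, but with an estimated correlation these gave adjusted p = 0.0831, 0.0831, 0.101 and 0.225. Cdk1, the mitotic kinase, rose by 4.48 (SE 0.40, n = 5 per group), Msr1 by 5.42 (SE 0.44), the neutrophil protein S100a8 by 6.70 (SE 0.66), and the cytokine Il6 by 5.23 (SE 0.50). Dmbt1 fell by 7.58 (SE 0.50), Scgb1a1 by 3.35 (SE 0.53) and Foxj1 by 2.46 (SE 0.45). In all, 6054 probe sets differed, 2887 higher and 3167 lower, against 3691 and 2498 with arrays centred on their medians (median shift 0.14).

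All 36 cell cycle genes rose at day 4 (mean 2.58, adjusted p = 4.08e-28, and adjusted p = 0.0458 with an estimated correlation), the 1 list of 23 called that held. Macrophage genes were higher in 20 of 23 (mean 2.58, adjusted p = 0.0831 with an estimated correlation), acute inflammation in 17 of 20 (3.03, 0.0831), neutrophils in 8 of 10 (2.83, 0.101), matrix in 21 of 31 (1.44, 0.198), hypoxia and glycolysis in 13 of 23 (0.87, 0.228), MHC class II in 6 of 8 (1.06, 0.216), cytotoxic cells in 6 of 11 (1.15, 0.216, and 0.777 without a filter) and alternative activation in 6 of 10 (1.498, 0.329). Secretory epithelium was lower in 18 of 19 (-2.998, adjusted p = 0.101 with an estimated correlation), ciliated epithelium in 7 of 9 (-2.02, 0.225), general epithelium in 16 of 27 (-0.99, 0.329), xenobiotic metabolism in 22 of 28 (-2.06, 0.0901), smooth muscle in 11 of 15 (-1.45, 0.313) and adipocytes in 15 of 15 (-3.88, 0.336). Arg1, which consumes arginine, rose by 7.21 (SE 0.95), Slfn4, a myeloid gene, by 8.10 (SE 0.54), the platelet chemokine Ppbp by 6.57 (SE 0.97), Timp1 by 6.25 (SE 0.50), C3ar1 by 4.82 (SE 0.38), Ctss by 3.82 (SE 0.22), Fscn1 by 3.68 (SE 0.24) and Col1a1 by 1.92 (SE 0.31). Lipf, a gastric lipase, fell by 10.83 (SE 0.44), Pth by 8.48 (SE 0.86), the salivary gene Dcpp1 by 8.25 (SE 0.49), the lipogenic gene Thrsp by 7.93 (SE 1.47), Cldn8, a tight junction protein, by 4.17 (SE 0.38), Cnn1 by 3.54 (SE 0.52), Chad by 3.33 (SE 0.48) and Ighm by 2.79 (SE 0.76). With the mean of its probe sets Ighm differed by -0.381 (adjusted p = 0.458, the highest of its alternatives). Gzmb rose by 1.31 (SE 0.28), and Cxcl9 differed by 0.18 (SE 0.41, adjusted p = 0.756).

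At day 14, isografts differed from native trachea in macrophage and MHC class II genes, which rose, while ciliated genes had a mean of 0.41 (adjusted p = 0.106) and were called without isograft replicate 1 (0.638, adjusted p = 0.0164). Clec7a, a fungal receptor of myeloid cells, rose by 4.09 (SE 0.37, n = 5 per group), Itgax, an integrin of dendritic cells, by 4.36 (SE 0.38), the macrophage elastase Mmp12 by 5.91 (SE 0.45), and Ctss, a protease of antigen processing, by 3.78 (SE 0.22). The mucosal peptide Tff2 fell by 5.01 (SE 0.32) and Dcpp1 by 7.20 (SE 0.49). Scgb1a1 and Foxj1 differed by -0.84 (SE 0.53, adjusted p = 0.234) and -0.12 (SE 0.45, adjusted p = 0.861). Of the 3935 probe sets that differed, 1652 were higher and 2283 lower. The split depended on the scaling, with 2757 higher and 1054 lower after centring on the scaling reference genes (median shift 0.27), 2504 and 1481 after centring on array medians (0.17), and 1998 and 1657 after repeated quantile normalization (0.11).

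Macrophage genes were higher in 19 and lower in 2 of 23 at day 14 (mean 2.08, adjusted p = 2.86e-18, and adjusted p = 0.0376 with an estimated correlation), and MHC class II genes higher in 7 of 8 (mean 1.61, adjusted p = 1.63e-09, and adjusted p = 0.027 with an estimated correlation). The other 15 called lists did not hold, among them matrix (1.08, adjusted p = 0.171 with an estimated correlation, 21 of 31 higher), interferon-gamma (0.86, 0.171, 13 of 24), MHC class I (0.58, 0.171), type I interferon (0.93, 0.193, 12 of 21), acute inflammation (1.25, 0.193, 10 of 20), smooth muscle (-1.25, 0.193, 12 of 15 lower) and secretory epithelium (-0.95, 0.502, 8 of 19 lower). S100a8, Slfn4, Arg1 and the chemokine Ccl8 rose by 4.82 (SE 0.66), 5.18 (SE 0.54), 4.45 (SE 0.95) and 4.70 (SE 0.49). Col1a1 rose by 1.85 (SE 0.31) and Cxcl9 by 2.29 (SE 0.41), while Acta2 fell by 0.99 (SE 0.23) and Cnn1 by 2.86 (SE 0.52). Sftpa1, a surfactant protein, fell by 5.60 (SE 0.27), Dcpp3 by 5.79 (SE 0.44), and Ucp1, the heat-producing protein of brown fat, by 5.26 (SE 1.59).

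Day 25 isografts still differed from native trachea in macrophage genes, with Gpnmb up by 4.39 (SE 0.38, n = 5 per group), Itgax by 4.48 (SE 0.38) and Mmp12 by 5.57 (SE 0.45). S100a8, its partner S100a9 and Slfn4 rose by 5.73 (SE 0.66), 5.04 (SE 0.62) and 5.85 (SE 0.54), and Ccl8 by 4.46 (SE 0.49). Sftpa1, Ucp1, Tff2 and Dcpp1 fell by 5.69 (SE 0.27), 5.63 (SE 1.59), 5.31 (SE 0.32) and 5.12 (SE 0.49). Scgb1a1, Foxj1 and Krt5 differed by -0.66 (SE 0.53), 0.31 (SE 0.45) and -0.54 (SE 0.59), with adjusted p from 0.411 to 0.673. Over omissions of 1 array Scgb1a1 ran from -0.879 to -0.088 (the last without isograft replicate 5), Foxj1 from -0.277 (without native replicate 5) to 0.742 (without native replicate 1) and Krt5 from -1.205 (without isograft replicate 5) to -0.143 (without isograft replicate 1), without a call. Here 2203 probe sets differed, 1228 higher and 975 lower, against 1706 and 522 with centring on the scaling reference genes (median shift 0.19). Their number was 1425 without native replicate 1.

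Macrophage genes rose in 18 of 23 cases at day 25 (mean 2.15, adjusted p = 2.1e-21, and adjusted p = 0.0238 with an estimated correlation) and MHC class II genes in 7 of 8 (mean 1.44, adjusted p = 1.72e-08, and adjusted p = 0.0238 with an estimated correlation). The 18 other called lists did not hold, among them matrix (1.02, adjusted p = 0.149 with an estimated correlation, 17 of 31 higher), complement (1.16, 0.149, 8 of 13), neutrophils (1.92, 0.149, 5 of 10), cell cycle (0.60, 0.312, 7 of 36) and endothelium (0.39, 0.478, 6 of 18, with the receptor Aplnr up by 1.74 and SE 0.31). Col1a1 rose by 1.86 (SE 0.31), Cxcl9 by 1.58 (SE 0.41), Tap1 by 1.54 (SE 0.28) and Rrm2, which makes DNA precursors, by 1.63 (SE 0.41).

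Allografts at day 4 compared with native trachea had interferon-gamma, acute inflammation and cell cycle genes called higher by camera and secretory and ciliated genes called lower. With an estimated correlation these gave adjusted p = 0.0733, 0.0717, 0.0717, 0.0956 and 0.178. Cxcl9 rose by 5.28 (SE 0.41, n = 5 per group), Klrd1 by 3.31 (SE 0.27), Gzmb by 2.23 (SE 0.28), Birc5 by 4.46 (SE 0.44) and S100a8 by 6.90 (SE 0.66). Lipf fell by 11.47 (SE 0.44), Dcpp1 by 8.92 (SE 0.49), Dmbt1 by 7.87 (SE 0.50), Tppp3 by 3.58 (SE 0.45) and Foxj1 by 2.54 (SE 0.45). There were 6128 differing probe sets, 3032 higher and 3096 lower. None of the 19 lists called by camera held with an estimated correlation, among them cell cycle (2.58, adjusted p = 0.0717 with an estimated correlation, 35 of 36 higher), interferon-gamma (1.91, 0.0733, 21 of 24), macrophages (2.92, 0.0717, 20 of 23), secretory epithelium (-3.11, 0.0956, 18 of 19 lower) and ciliated epithelium (-2.03, 0.178, 8 of 9). By fry, a test of the list alone, these had adjusted p from 4.81e-12 to 1.36e-06. Slfn4, Arg1, Ppbp, Rpgrip1 and Timp1 rose by 7.77 (SE 0.54), 7.70 (SE 0.95), 7.37 (SE 0.97), 6.95 (SE 0.43) and 5.92 (SE 0.50), Rpgrip1 not on its other probe sets.

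At day 14, allografts showed higher cytotoxic, interferon-gamma, antigen presentation and matrix genes than native trachea and lower secretory genes. Cxcl9 rose by 7.44 (SE 0.41, n = 5 per group), the chemokine Ccl5 by 5.07 (SE 0.38), Gzmb by 4.72 (SE 0.28), Ido1 by 5.61 (SE 0.33), and Il7r, a survival receptor of T cells, by 2.96 (SE 0.37). Lipf (-11.48, SE 0.44), Tg (-10.44, SE 0.55), Dmbt1 (-10.22, SE 0.50) and Pth (-10.09, SE 0.86) fell, Scgb1a1 by 7.69 (SE 0.53) and Cnn1 by 4.88 (SE 0.52). Col1a1 rose by 2.78 (SE 0.31). Col2a1 fell by 1.70 (SE 0.56, adjusted p = 0.0138), but not without allograft replicate 1 (-1.35, adjusted p = 0.0522). Of 6305 differing probe sets 2973 were higher and 3332 lower, against 3432 and 2453 with centring on the scaling reference genes (median shift 0.15) and 3612 and 2678 with centring on array medians (0.13).

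Of 23 lists called at day 14, 13 held with an estimated correlation. All 24 interferon-gamma genes rose (3.22, adjusted p = 0.0116 with an estimated correlation), as did 11 of 11 cytotoxic genes (3.17, 0.0116, and 2.204 without a filter), 9 of 9 MHC class I genes (1.75, 0.0116), the 4 measured of 16 checkpoint genes (3.11, 0.0116, and 1.214 without a filter), 7 of 8 MHC class II genes (2.31, 0.0272), 20 of 23 macrophage genes (2.99, 0.0272), 11 of 13 complement genes (2.11, 0.0451), 9 of 12 dendritic cell genes (1.45, 0.0451), 18 of 20 acute inflammation genes (2.61, 0.048) and 26 of 31 matrix genes (1.83, 0.0467). Lower were 19 of 19 secretory genes (-5.76, adjusted p = 0.0116 with an estimated correlation), 23 of 27 general epithelium genes (-2.35, 0.0467) and 21 of 28 xenobiotic metabolism genes (-2.20, 0.0434). Ciliated epithelium (-2.24, 7 of 9 lower) gave adjusted p = 0.135 with an estimated correlation, and cartilage (-1.99, 18 of 21 lower) gave adjusted p = 0.268 with an estimated correlation. C1qtnf3, Rpgrip1, Ccl8 and C1qb rose by 6.55 (SE 0.39), 7.89 (SE 0.43), 6.26 (SE 0.49) and 4.18 (SE 0.25), Rpgrip1 not on its other probe sets.

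By day 25, allografts differed from native trachea in general and secretory epithelial genes, which fell, and in cytotoxic, B cell and macrophage genes, which rose. Bpifa1 fell by 11.76 (SE 0.43, n = 5 per group), Scgb1a1 by 10.42 (SE 0.53), Krt18, a keratin of simple epithelium, by 7.21 (SE 0.35), Krt15 by 7.10 (SE 0.62) and Krt5 by 5.52 (SE 0.59). Lipf, Tg and Ltf fell by 11.51 (SE 0.44), 11.01 (SE 0.55) and 10.61 (SE 0.53), and Acta2 by 1.96 (SE 0.23). Cxcl9, Ighm, Ly86, Il7r and Col1a1 rose by 7.79 (SE 0.41), 5.13 (SE 0.76), 5.86 (SE 0.39), 3.40 (SE 0.37) and 2.67 (SE 0.31). In all, 4920 probe sets differed, 2417 higher and 2503 lower, against 2621 and 1834 with centring on the scaling reference genes (median shift 0.13) and 2774 and 2091 with centring on array medians.

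Of 22 lists called at day 25, 12 held with an estimated correlation. Lower were 25 of 27 general epithelium genes (-4.14, adjusted p = 0.00871 with an estimated correlation), 18 of 19 secretory genes (-6.80, 0.00871) and 20 of 28 xenobiotic metabolism genes (-1.97, 0.0387). Higher were 11 of 11 cytotoxic genes (2.87, adjusted p = 0.0109 with an estimated correlation, and 1.914 without a filter), 9 of 9 MHC class I genes (1.65, 0.0109), 7 of 8 MHC class II genes (2.70, 0.0146), 20 of 23 macrophage genes (3.07, 0.0177), 20 of 24 interferon-gamma genes (2.39, 0.0177), 9 of 12 dendritic cell genes (1.63, 0.0266), 8 of 8 B and plasma cell genes (2.82, 0.0466), 10 of 13 complement genes (2.09, 0.0394) and 27 of 31 matrix genes (1.81, 0.0394). Smooth muscle (-2.14, 13 of 15 lower) gave adjusted p = 0.0569 with an estimated correlation, ciliated epithelium (-2.10) 0.118 and basal epithelium (-2.46) 0.291. Mast cells (-1.48, 3 of the 4 measured of 11 lower, and -0.744 without a filter, with the histamine-forming enzyme Hdc down by -3.55 and SE 0.48) gave adjusted p = 0.109 with an estimated correlation.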

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

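The regroupings of arrays were planned before the results they test were seen, and the tests of the 3 patterns weighed at the end of this part were chosen after. Results are given here when 1 array lay far from the other 4 of its group by Dixon's test, or when the allograft-isograft difference changed between days by limma or, for gene lists, by camera with an estimated correlation. Dixon's test was run on 308 sets of 5 arrays (224 of list levels and 84 of gene levels) and singled out 24, while chance singles out about 1 in 20 (15.4).

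Native replicate 5 had low complement (6.16), secretory epithelium (11.25), ciliated epithelium (6.23) and adipocyte (10.08) levels, and high basal epithelium (8.73) and skin (9.21) levels. Day 25 isograft replicate 5 had low secretory epithelium (9.42) and Scgb1a1 (11.49), and high basal epithelium (8.95), skin (8.0, against 4.06 to 4.35 in its group) and hypoxia and glycolysis (8.5, against 8.16 to 8.26) levels. Day 25 isograft replicate 1 had high interferon-gamma response (7.27) and checkpoint (5.09) levels and a low cartilage level (7.42). Cartilage was also low in native replicate 3 (7.67). Adipocyte levels were high in day 4 isograft replicate 2 (10.19) and day 4 allograft replicate 1 (8.73). Thyroid levels were low in day 14 isograft replicate 5 (6.42) and high for the group in day 25 allograft replicate 5 (3.17). In day 4 allograft replicate 5 acute inflammation was low (7.49) and Foxj1 high (6.53). Among day 25 allografts, replicate 1 had high ciliated epithelium (5.52) and low Col1a1 (13.13), and replicate 2 had low general epithelium (3.82).

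Between days 4 and 14 the difference changed for 873 probe sets. Lists that changed were cytotoxic and NK cells (1.79), MHC class I (0.753), checkpoints (2.52), general epithelium (-1.63), secretory epithelium (-4.697), ciliated epithelium (-2.641), cell cycle (1.375), hypoxia and glycolysis (0.951) and xenobiotic metabolism (-1.408). Genes were Ido1 (5.528), Ubd (3.781), Ccl7 (3.624), Pcsk5 (3.621), Gzmb (3.59), Cd3e (1.447), Pth (-12.292), Tg (-9.043), Scgb3a2 (-8.371), Dmbt1 (-7.916), Scgb3a1 (-7.599), Scgb1a1 (-7.031) and Foxj1 (-2.688).

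Between days 14 and 25 it changed for 146 probe sets. Lists were B and plasma cells (1.488), neutrophils (-2.297, a list that includes Ltf), checkpoints (-1.76, but -0.424 without a filter), general epithelium (-1.816), cartilage (2.839) and cell cycle (-1.266). Genes were Penk (5.122), Otor (4.876), Mia (4.547), Col9a1 (4.422), Matn4 (4.23), Col2a1 (3.167), Ltf (-5.863), Krt19 (-5.383), Ido1 (-5.176), Krt7 (-4.952), Wfdc2 (-4.801), Krt5 (-4.438), Scgb1a1 (-2.91) and Acta2 (-1.6).

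Between days 4 and 25 it changed for 708 probe sets. Lists were cytotoxic and NK cells (1.719), B and plasma cells (2.128), MHC class II (1.027), general epithelium (-3.446), secretory epithelium (-5.766) and ciliated epithelium (-2.387). Genes were Iglv1 (5.311), Igkv9-120 (3.591), Ighg3 (3.536), Egfl6 (3.41), Ptx3 (3.355), Gzmb (2.397), Pth (-12.59), Bpifa1 (-11.264), Tg (-10.539), Scgb1a1 (-9.942), Scgb3a1 (-9.888), Krt5 (-4.939), Foxj1 (-3.329) and Acta2 (-1.436).

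Each count of probe sets was compared with counts from 100 splits of the same arrays into groups of the same sizes, the real split included, with the compared arrays fitted alone. In the allograft-isograft comparisons the real split called 51, 2306 and 1429 probe sets at days 4, 14 and 25, and the highest other split 33, 68 and 5. For isografts against native trachea the real splits gave 5592, 2915 and 1553 and the highest others 658, 1246 and 2. For allografts against native trachea they gave 5710, 5802 and 3967 against 63, 1980 and 562. In each of these 9 comparisons 1 split, the real one, called as many, so chance can be excluded. The changes of difference gave 1133 against 366 from day 4 to day 14 and 681 against 12 from day 4 to day 25, each with 1 split of 100 as large. From day 14 to day 25, 2 of 100 splits called as many, the real one with 104 and another with 234. Whether the larger count comes from a structure of the samples was not tested. For the changes of difference the splits also exchanged arrays between days and graft types. So they cannot exclude chance for a change of difference alone.

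The first pattern weighed was 40 genes that differed alike at all 3 days, 35 higher and 5 lower in allografts. An interferon response is a candidate explanation for part of them, since 13 were in the 2 interferon lists where chance draws 0.217 (exact hypergeometric p = 5.54e-21). The 27 outside those lists still hold genes described above as interferon-inducible (Trim34a) or interferon-induced (Ifi44l), and the NK cell receptor chain Klrd1. Of the 27, 22 had no called change of difference between days. A strain or donor variant read by a single probe set is a candidate explanation for some of the 27. Of the other kept probe sets of all 40 genes, 52.6% (10 of 19) differed alike by at least 0.5 of the named probe set's difference at day 14, and of those outside the lists 43.8% (7 of 16), under the 0.5 set for a variant. These 16 probe sets belong to 13 genes, and the share does not say which of the 27 genes carry a variant. The design confounds donor and recipient genotype with the groups, so for the 40 genes as a whole a variant and a graft response cannot be told apart.

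The second pattern was the low level of Tg and Pth in late allografts. Less neighbouring tissue carried with the allografts stays open, since at day 14 the adipocyte list differed by -0.06 (SE 1.1) and the thyroid list by -4.98 (SE 0.47), a gap of 4.92 (SE 0.93), but skeletal muscle differed by -3.28 (SE 0.7, exact p = 0.00794, adjusted p = 0.274 by camera with an estimated correlation) and skin by -1.59 (SE 0.63, from 5 of 16 markers, and -0.53 without a filter). At day 25 adipocytes, muscle and skin differed by 0.89 (SE 0.96), -0.8 (SE 1.58) and -0.76 (SE 0.78), and muscle by -2.132 without allograft replicate 1, a call by camera (adjusted p = 0.000265). Loss of epithelium from the graft stays open too, since the test made of it, 4 of 4 airway epithelium lists lower at day 25 by camera (basal epithelium with adjusted p = 0.184 with an estimated correlation) and the Tg change of difference called, restated values already seen. Thyroid tissue lost on its own, or attacked by the recipient, was not tested.

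The third pattern was the cartilage list, low in allografts at day 14 and not at day 25, with a rise of 2.64 (SE 0.42) between these allografts. Dilution by infiltrating cells is argued against as the whole cause only as far as the matrix, smooth muscle and endothelium lists stand for the other graft tissue. These lists did not rise with cartilage (-0.02, -0.29 and -0.26), a gap of 2.83 (SE 0.39) to their mean. They also had changes of their own. Matrix averaged 9.16 in native trachea and 11 in day 14 allografts, and smooth muscle averaged 8.99 and 7.14. The leukocyte lists went both ways, T cells by 0.28, cytotoxic cells by -0.3, macrophages by 0.09, B and plasma cells by 1.84 (SE 0.4) and neutrophils by -1.91 (SE 0.21), and skeletal muscle moved by 2.31 (SE 1.45), so a part played by fewer neutrophils stays open. A single array is also argued against, since the lowest change of the allograft-isograft difference with 1 array left out was 2.558. No biological explanation was tested.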

How the results depend on the processing

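All alternatives below were planned except the removal of the 2 arrays that stood apart, which was chosen after seeing the data. The cause of the changes below was not tested, except where fewer probe sets tested, a stricter threshold or fewer arrays follow from the alternative's own construction. The pseudocount was not run, because the deposited values are already log2.

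Of 409 named gene results 341 were called. With array weights 0 of these limma calls were lost and 7 were gained, with an intensity trend and robust variance 1 was lost, after quantile normalization 4 were lost and 1 gained, after median centring 1 was lost and after centring on the scaling reference genes 10. With the mean of a gene's probe sets 7 were lost and 2 gained, and without a filter 9 were lost and 5 gained. Of 372 list results 227 were called, of which 156 were lost with an estimated correlation and 32 with the rotation test fry, which gained 21. Omissions of 1 array ended 121 of 3820 gene calls and 87 of 2820 list calls, and added 5 and 105.

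Without a filter 10007 and 6154 probe sets differed from native trachea in day 4 and day 14 isografts. The stricter filter gave 3875 and 2530 there, and 4033, 3952 and 3171 in allografts at days 4, 14 and 25. Array weights gave 3549 in day 25 isografts, and 1433 and 1287 changes of difference from day 4 to days 14 and 25. At an adjusted p under 0.01 the allograft-isograft counts were 52 and 1608 at days 4 and 14, the isograft counts 1845 and 901 at days 14 and 25, the day 25 allograft count 3205, and the changes of difference 447, 69 and 438 (days 14 against 4, 25 against 14, 25 against 4). At least 2-fold were 1496 and 1251 in allografts against isografts at days 14 and 25, 3032, 1673 and 1159 in isografts and 3203, 3286 and 2524 in allografts against native trachea, and 226 genes higher at both days 14 and 25. With only the 10 arrays compared, 51 probe sets differed at day 4.

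With an estimated correlation the number of lists called was 1, 9 and 10 for allografts against isografts (8, 22 and 18 with the preset correlation), 1, 2 and 2 for isografts against native trachea (23, 17 and 20), 0, 13 and 12 for allografts against native trachea (19, 23 and 22), and 9, 6 and 6 for the changes of difference (18, 18 and 19). By fry, 1 list was called for allografts against isografts at day 4 and 8 for the change from day 14 to day 25.

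Leaving out 1 array moved the day 25 isograft-native count between 1425 (without native replicate 1) and 2753 (without native replicate 5), and the changes from day 14 to day 25 between 96 (without day 14 allograft replicate 3) and 189 (without day 25 allograft replicate 5). The number of lists called at day 4 ran from 5 (without isograft replicate 4) to 11 (without isograft replicate 3). Without the 2 arrays that stood apart together the allograft-isograft counts were 87, 2721 and 2069, the isograft-native counts 6237, 4826 and 2714, the allograft-native counts 6445, 6722 and 5414, and the changes of difference 1067, 123 and 884.

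The direction reversed in 2 cases, that of the value for Ctse and that given by camera, which ranks a list against the other genes, for skeletal muscle. Ctse at day 4 was 0.374 with the stricter filter (adjusted p = 1, range over its alternatives 0.00623 to 1), where another of its probe sets represented it. The change of the difference of the skeletal muscle (neighbouring tissue) list from day 4 to day 25 was -1.715 and lower by camera without day 25 allograft replicate 1 (adjusted p = 0.0155), against a mean of -0.39 with it that camera ranked higher (adjusted p = 0.888). It was 0.236 without replicate 3 (adjusted p = 0.304). Over all its alternatives the adjusted p ran from 0.0155 to 0.998.

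The labels number the replicates of each group but do not say whether arrays with the same number belong together. As a replicate block the numbers gave 86, 2540 and 2040 for allografts against isografts, 6061, 3991 and 2292 for isografts and 6132, 6340 and 4956 for allografts against native trachea, and 900, 168 and 707 changes of difference. The block fits the same effect of a number in all 7 groups, so it cannot take up a pairing within day 4 alone. Between the day 4 grafts the mean correlation was 0.261 for arrays with the same number and -0.062 for other arrays. Correlations of the deviations from the group mean between arrays with the same number ran from 0.05 to 0.47 between the day 4 grafts, where the own number was best for 4 of 5, from -0.42 to 0.35 at day 14 (1 of 5) and from -0.15 to 0.3 at day 25 (2 of 5), and with native trachea from -0.35 to 0.23 (0 to 2 of 5).

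Signal over background limits the dim genes. Ifng, below the filter, differed by 2.07 at day 14 and 0.85 at day 25 without a filter, and folds of genes that fall to values of 2 to 4, such as Bpifa1 and Scgb1a1 at day 25, depend on the background model.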

Other observations

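None of the values in this part comes with a test of an explanation, and the genes were chosen after their values were seen. Some genes had ranges in the 15 allografts that lay apart from those of the 20 other arrays. Rpgrip1, on its named probe set, ran from 9.48 to 11.74 in allografts and from 2.29 to 5.24 in the other arrays, while its 3 other probe sets lay between 2.44 and 4.3 in all arrays. Trim34a ran from 5.25 to 7.76 against 2.86 to 4.18, and its other probe set from 4.24 to 5.5 against 3.7 to 5.63. Hal ran from 2.43 to 3.09 against 3.3 to 8.13, and H2-Ea from 6.21 to 7.78 against 7.93 to 9.84. A second H2-Ea probe set ran from 1.71 to 7.19 against 7.84 to 10.68, and 1 more, below the filter, did not separate the arrays (3.19 to 3.8 against 2.91 to 4.38).

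The levels of Tg, Pth and Lipf were higher in isografts at days 14 and 25 than at day 4, and in allografts they were not. Tg averaged 14.46 in native trachea, 8.66, 12.39 and 13.31 in isografts at days 4, 14 and 25, and 9.34, 4.02 and 3.45 in allografts. Pth averaged 12.78 in native trachea, 4.3, 11.63 and 11.93 in isografts and 7.65, 2.69 and 2.69 in allografts. Lipf averaged 13.29 in native trachea, 2.45, 8.4 and 9.31 in isografts and 1.82, 1.81 and 1.78 in allografts. Zic1, a developmental transcription factor, averaged 2.89 in native trachea, 4, 5.02 and 4.88 in isografts and 5.3, 8.52 and 7.83 in allografts.

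Mast cell markers, 4 of 11 above the filter, averaged 6.21 in native trachea, 5.22, 5.98 and 5.9 in isografts at days 4, 14 and 25, and 5.54, 5.07 and 4.73 in allografts. Skeletal muscle markers in day 25 allografts ran from 3.77 to 11.58, the widest range of any group for that list, and their mean was 6.27 (SD 3.22). Cartilage markers averaged 8.61 in native trachea, 7.59, 8.69 and 8.49 in isografts and 7.79, 6.62 and 9.27 in allografts. The 3 Xist probe sets lay between 6.8 and 9.75 in day 14 allograft replicate 3, against 2.96 to 3.56 in the 4 other arrays of its group, and between 3.27 and 8.51 in native replicate 2. The Y-linked gene Eif2s3y lay between 6.64 and 8.03 in all 35 arrays, these 2 included.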
